A study of Homo sapiens with 7 samples.

How the data were processed

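DNA methylation was measured by enhanced reduced representation bisulfite sequencing. In it, genomic DNA is cut at CpG-rich sites and treated with bisulfite, so that unmethylated cytosine is read as T and methylated cytosine as C. A read gives only C or T, so methylated cytosine was not measured apart from any oxidised form that is also read as C. The cells were HUES8, an established human embryonic stem cell line, either wild type (WT) or with TET1, TET2 and TET3 knocked out together (TKO). Per the labels, they were sampled as stem cells (SC, day 0), cardiac mesoderm (CME, day 3), cardiac progenitors (CP, day 8) and beating cardiomyocytes (CM, day 14, WT). There were 7 libraries, with 1 library per genotype and stage. Groups were taken from the sample titles. The WT CM library is placed at day 14 by the series text and at day 15 by its description, and its source label names the CME stage, so its stage rests on its title.

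Per the labels' protocols, a core facility aligned the reads and extracted the methylation calls, and per the submitters' processing notes the genome build was hg19. The aligner, the caller and their versions are not given in the sources used here. The deposited files list each CpG cytosine by strand with its coverage, a read count per cytosine that the authors did not normalize, as far as the values show. They also give the percent of reads that the authors' caller read as C and as T, per the file headers. The lowest coverage count in every file was 10. Coverage multiplied by these percentages gave whole numbers of reads in 100% of the lines, within the rounding of percentages given to 3 decimals, and between 0.0147% and 0.0183% of reads carried another base. Since the files hold neither sequence nor expression, the knockout itself was not checked here.

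The methylated and unmethylated reads of both strands of a CpG were summed. The methylation level is methylated reads divided by methylated plus unmethylated reads. Total coverage, as the sum of reads over listed cytosines, was 120742115 for WT SC, 141999649 for WT CME, 158372334 for WT CP, 156566713 for WT CM, 197312658 for TKO SC, 213058905 for TKO CME and 149053464 for TKO CP. Of 2587280 CpGs seen in any library, 1734500 had 10 or more reads in all 7, and 1734462 of these lay outside the mitochondrial genome. The mitochondrial CpGs were kept apart, and their share of C reads was used as a measure of cytosine left unconverted.

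Summed reads were compared in 1 kb tiles with 5 or more CpGs that had 10 or more reads in all 7 libraries. This gave 85087 tiles with a median of 9 CpGs. For each of 9 pairs of libraries, Fisher's exact test (two-sided) was run on the methylated and unmethylated reads of each tile, with Benjamini-Hochberg adjustment over the tiles. A tile was called higher or lower at an adjusted p below 0.01 and a difference of 25 percentage points or more. With 1 library per group these tests compare libraries, not conditions. They cover counting error only, and can understate it. A read that spans several CpGs counts at each of them, and PCR copies are not independent molecules. The read numbers given for tiles are such sums over CpGs, so the p-values and intervals based on them can be too small. Intervals are 95% Wilson intervals, and a level of 0 is given with its upper limit and with the level that 3 reads would make. The change of the genotype difference between stages was tested per tile with a z test on the reads, at the same adjusted p and size.

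As a measure of technical noise within a library, its plus and minus strand reads were compared in the same way over tiles with 5 or more CpGs read 10 or more times on each strand. This called 0.0982% to 0.375% of tiles. It covers another, smaller set of tiles and holds no difference between libraries or cultures, so it sets no background for the comparisons. The test was checked on simulated reads for TKO CP minus WT CP over 85087 tiles. It recovered 100 of 100 tiles changed by 40 points and 89 of 100 changed by 30 points, and it called 1 of 84887 unchanged tiles. TKO was also compared with WT in 1 linear model of genotype plus stage with limma, which leaves 2 residual degrees of freedom, at the same adjusted p and a mean difference of 25 points. On simulated reads over 85087 tiles, for TKO minus WT with stage as block, it recovered 99 of 100 tiles changed by 40 points and 94 of 100 changed by 30 points on the arcsine square root scale. On the logit scale it recovered 86 and 74, and neither called any of 84887 unchanged tiles. The arcsine scale was chosen from this simulation before the fit was run on the data. R 4.3.3 and limma 3.58.1, and Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9 were used.

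The tiles named were fixed before the data were examined as the 6 with the largest rise and the 6 with the largest fall among the called tiles, for the 3 genotype comparisons and for WT CM minus WT SC. Runs of called tiles whose starts lay at most 2000 bp apart were joined into regions. The regions with the most called tiles are named by a rule chosen after their values were seen. No gene annotation or sequence of build hg19 was used here, and the gene table at hand is on GRCh38.p14, so positions are given without gene names. Promoter windows and the gene lists fixed beforehand, which cover cardiac, mesoderm, sarcomere, pluripotency, neural, endoderm, vascular, signalling, methylation machinery, germline, HOX, imprinted and housekeeping genes, were not analysed here for the same reason.

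The alternatives planned were a minimum of 20 reads, the CpGs of the 2 libraries compared, a mean over CpGs in place of summed reads, reads thinned to a common depth, agreement of both strands, subtraction of the median difference, removal of CpGs above the 99.9th percentile of coverage, 500 bp tiles and a difference of 40 points. For the overall level they were all CpGs of a library, a minimum of 20 reads and the autosomes. Correction for the mitochondrial share of C, weighting the overall level by reads, thinning in the comparison of genotype differences between CP and SC, and the fit with stage as block were added after seeing the data.

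Sample descriptions end in the same suffix for 2 libraries, WT SC and WT CME, and lack it for the other 5. Read coverage across CpGs had a Spearman correlation of 0.944 between these 2, against 0.119 to 0.626 between them and the others and 0.555 to 0.908 among the others. These correlations are across CpGs, which are not independent replicates. The libraries were therefore treated as possibly belonging to 2 sets. TKO CME and TKO CP had correlations of 0.788 to 0.908 with WT CP and WT CM, and were taken as 1 set with them. TKO SC lacks the suffix, and its correlation was 0.119 with WT SC and 0.129 with WT CME, against 0.797 with TKO CME, 0.644 with WT CP, 0.633 with TKO CP and 0.555 with WT CM. Its coverage is thus nearer to the libraries without the suffix, but 0.555 is below the 0.616 and 0.626 of WT SC and WT CME with WT CM, so its set is less sure. No label gives the order in which the sets were made. If there are 2 sets, the genotype comparisons at SC and CME and the WT changes from CME to CP and from SC to CM run across them.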

Results

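Methylation at CpGs was profiled in WT and TKO HUES8 cells along a cardiac differentiation that used an activator and then an inhibitor of Wnt signalling. The TET enzymes oxidise 5-methylcytosine, a step on the way to unmethylated cytosine, so the design asks which sites gain or lose methylation during differentiation when all 3 enzymes are missing. WT cells were sampled at 4 stages and TKO cells at 3, because TKO cells form no beating cardiomyocytes, per the series text. The 7 libraries held between 1945964 (TKO CP) and 2360122 (WT CME) CpGs each. Over the 1734462 shared CpGs the median coverage was 45 reads in WT SC, 53 in WT CME, 70 in WT CP, 69 in WT CM, 87 in TKO SC, 94 in TKO CME and 69 in TKO CP. No group has a replicate library, so no difference below can be set against replicate spread.

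The overall level diverged between the genotypes. In WT cells the mean level over CpGs was 41.8% at SC, 42.5% at CME, 39.3% at CP and 39.7% at CM. In TKO cells it was 44.3% at SC, 44.7% at CME and 46.8% at CP. TKO thus lay 2.52 points above WT at SC, 2.28 points at CME and 7.55 points at CP. The share of CpGs over 80% was 39.3% in WT CME and 34.97% in WT CP, whereas it was 39.9% in TKO CME and 43.8% in TKO CP. CpGs under 20% made up 51.9% to 54.1% in WT libraries and 46.4% to 47.4% in TKO libraries. When each read was weighted equally, TKO remained above WT at SC (36.7% against 33.9%) and at CP (37.3% against 28.0%), but TKO CME lay below WT CME (33.3% against 33.8%). The widest 95% Wilson interval of these weighted levels was ± 0.00928 points. It covers counting error only and can understate it, since a read counts at each CpG it spans. Over all CpGs of each library, in place of the shared ones, TKO stood at 48.7% at SC, 48.2% at CME and 48.03% at CP. The rise of TKO to CP thus depends on the CpGs used.

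**Figure D1:**
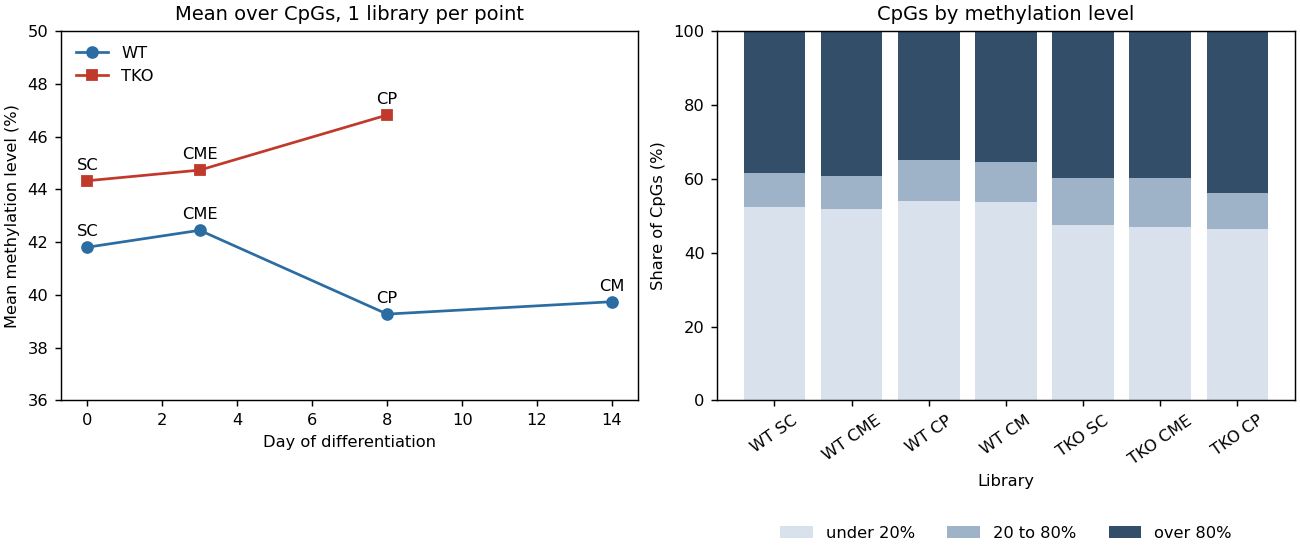
Left, mean methylation level (%) over 1734462 CpGs against day of differentiation, with 1 point per library, WT as circles and TKO as squares; the axis starts above 0. Right, share of CpGs (%) under 20%, from 20 to 80% and over 80% in each library; the share over 80% was 34.97% in WT CP and 43.8% in TKO CP.

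In stem cells, differences of 25 points or more were mostly gains in TKO, while smaller differences were more often decreases. Of 85087 tiles, 5324 (6.26%) were higher and 101 were lower in TKO SC than in WT SC. By adjusted p alone, whatever the size, 14578 were higher and 20114 lower, and the median difference was -0.929 points. The mitochondrial share of C was 1.504% in WT SC and 0.142% in TKO SC, a gap no smaller than that median difference. These counts were not corrected for it. Tiles over 80% in WT CP differed by a median of -3.10 points, with 20.4% of them above WT SC. Unconverted cytosine acts only on unmethylated reads, so it can raise a level by no more than its share. The median fall in these tiles exceeds the 1.504% of WT SC, which argues against conversion as the whole cause there. The higher tiles had a median level of 16.4% in WT SC and 79.0% in TKO SC, and they were also low in the later WT libraries, at 9.84% in CP and 11.5% in CM. Tiles that WT CP held under 20% were higher by 25 points in 12.03% of cases (3742 of 31114) and those at 20 to 80% in 11.3% (1573 of 13942). Of the 40031 tiles over 80%, which have little room to rise, 9 were. The largest rise was at chromosome 17, 16650001 to 16651000, where 7 CpGs stood at 1.13% of 444 reads in WT SC and 94.1% of 220 reads in TKO SC (adjusted p = 1.34e-146, Fisher's exact test). The next were tiles starting at 39687001 on chromosome 19 (3.11% against 95.7%), 194406001 on chromosome 3 (1.67% against 93.8%), 82763001 on X (2.00% against 93.9%), 47547001 on chromosome 17 (0.733% against 92.2%) and 152586001 on X (6.73% against 97.6%).

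Losses of 25 points or more in TKO stem cells were few. The tile at 114428001 on chromosome 13 stood at 85.4% in WT SC and 10.4% in TKO SC, and that at 21657001 on chromosome 19 at 95.1% and 20.8%. The tile at 47930001 on X stood at 73.6% in WT SC and 1.09% in TKO SC, and that at 88124001 on chromosome 2 at 70.8% and 1.49%. The other named losses were at 194768001 on chromosome 2 (100% of 73 reads against 33.9%) and 11849001 on chromosome 19 (66.9% against 9.53%). Of the 101 losses (0.119% of tiles), 50 were also lower at CME and 23 at CP, where independent lists would share 0.0855 and 0.0463. Those numbers are a low bar, since tiles low in WT have no room to fall. A fixed difference between the WT and TKO cells would raise both overlaps. Of the 38 losses that could be read on each strand, 24 passed on both. WT SC carries the suffix of its library description and TKO SC does not, so the comparison possibly runs across library sets. At a threshold of 40 points the counts were 3393 higher and 20 lower.

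At the mesoderm stage the genotype difference resembled that in stem cells. In TKO CME, 5121 tiles (6.02%) were higher and 72 were lower than in WT CME. By adjusted p alone, 14060 were higher and 23587 lower, with a median difference of -1.04 points over all tiles and -3.55 points in tiles over 80% in WT CP. These counts were not corrected for the mitochondrial share of C, which was 1.46% in WT CME and 0.397% in TKO CME. In the tiles over 80% the median fall again exceeds the share in WT CME. Of the 5324 tiles higher at SC, 4755 (89.3%) were higher at CME, where 320 would be shared by independent lists. That number is a low bar, since tiles already high in WT have little room to rise. The pairs share no library, but both set TKO without the suffix against WT with it. A set effect or a fixed difference between the WT and TKO cells would raise this overlap too. The largest rise was at 103345001 on chromosome 12, where 5 CpGs stood at 7.83% of 217 reads in WT CME and 100% of 124 reads in TKO CME. It was followed by 194406001 on chromosome 3 (2.03% against 94.0%), 92702001 on chromosome 11 (1.91% against 93.1%), 8893001 on chromosome 4 (3.92% against 94.6%), 2985001 on chromosome 1 (3.00% against 93.6%) and 149674001 on chromosome 1 (4.06% against 94.6%). The largest falls were at 47930001 on X (93.1% against 1.36%) and 88124001 on chromosome 2 (81.8% against 1.41%). Then came 114428001 on chromosome 13 (80.2% against 5.56%), 11849001 on chromosome 19 (72.2% against 8.75%), 21657001 on chromosome 19 (92.5% against 30.4%) and 4681001 on chromosome 7 (91.1% against 33.4%). Lower tiles made up 0.0846%, and the comparison again possibly runs across library sets. At 40 points 3212 tiles were higher and 18 lower.

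By calls of 25 points or more, the genotypes differed most at the progenitor stage. In TKO CP, 10209 tiles (11.998%) were higher and 39 were lower than in WT CP, and neither library carries the suffix of WT SC and WT CME. By adjusted p alone, 33428 were higher and 3058 lower, which is 36486 tiles against 37647 at CME. Of the tiles higher at SC, 5061 (95.1%) were higher at CP. Another 5148 tiles were higher at CP and not at SC. Their median level was 71.8% in WT SC and 39.9% in WT CP, and 82.0% in TKO SC and 87.4% in TKO CP. In 2247 of them WT CP lay 25 points or more below WT SC, and in 485 TKO CP lay 25 points or more above TKO SC. Both applied to 12 tiles and neither to 2428. Tiles at 20 to 80% in WT SC were higher in TKO CP in 44.0% of cases (4610 of 10467), those under 20% in 13.1% (3877 of 29540) and those over 80% in 3.82% (1722 of 45080).

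The largest rise at CP was at 93956001 on chromosome 9, where 14 CpGs stood at 0.214% of 1401 reads in WT CP and 96.7% of 760 reads in TKO CP. Tiles at 86548001 on chromosome 16 (2.58% against 99.0%), 21649001 on chromosome 13 (0.985% against 97.2%), 138277001 on X (0.654% against 96.9%), 16650001 on chromosome 17 (1.06% against 97.2%) and 133995001 on chromosome 11 (1.07% against 96.8%) followed. The tile on X at 138277001 was at 22.6% in TKO SC and 18.1% in TKO CME. The largest falls were again at 47930001 on X (86.5% against 0.767%) and 88124001 on chromosome 2 (76.1% against 1.10%). They were followed by 28725001 on chromosome 6 (81.9% against 25.7%), 4681001 on chromosome 7 (89.7% against 33.7%) and 238648001 on chromosome 1 (89.8% against 37.98%). At 58287001 on chromosome 6, 7 CpGs stood at 52.2% of 90 reads in WT CP and at 0 of 84 reads in TKO CP. The 95% Wilson upper limit was 4.37%, where 3 reads would make 3.57%. These reads are summed over the CpGs, so the limit is too low where a read spans several. Over the 48 places in these lists and those for WT cardiomyocytes, the highest adjusted p was 6.00e-17 (Fisher's exact test). The fewest reads, summed over the CpGs of a tile, were 73. At 40 points 6631 tiles were higher and 12 lower at CP.

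Tested directly, the TKO minus WT difference was larger at CP than at SC in 4827 tiles and smaller in 92. It was larger at CP than at CME in 4821 tiles and smaller in 50. Between CME and SC it was larger in 22 tiles and smaller in 40. The WT libraries of SC and CME carry the suffix and that of CP does not, so a change of the difference to CP is confounded with a possible change of set in WT. In 2508 of the 4827 tiles WT CP was at least 25 points below WT SC, and in 847 TKO CP was at least 25 points above TKO SC. Higher levels in TKO were found at all 3 stages in 4645 of the 10517 tiles higher at any stage, and lower levels at all 3 stages in 21 of 136. In a single fit of genotype and stage over the libraries, added after seeing the data, 5298 tiles were higher and 29 lower in TKO, among them 4569 of the 4645 and 21 of the 21. The stages of this fit are not replicate cultures. At those 21 tiles the medians were 66.9%, 72.1% and 62.0% in WT SC, CME and CP, and 9.53%, 8.75% and 6.24% in TKO.

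**Figure D2:**
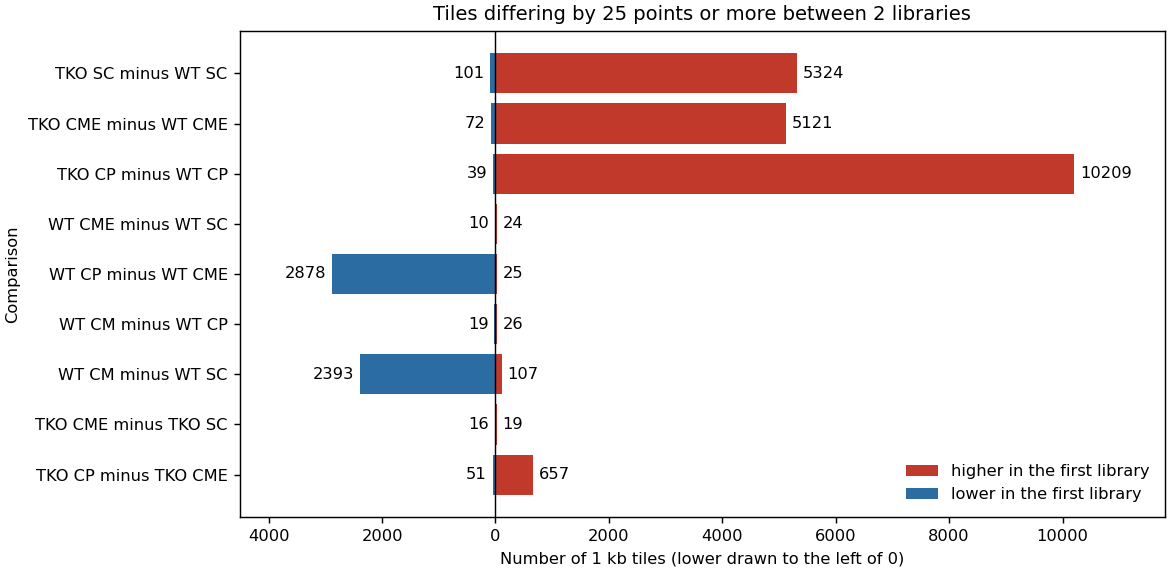
Number of 1 kb tiles, of 85087, that were higher (bars to the right) or lower (bars to the left) by 25 points or more in the first library of each pair, with the pairs on the vertical axis. The longest bar is the 10209 tiles higher in TKO CP than in WT CP.

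Among the WT libraries, most tiles that differed were lower in CP than in CME, and few differed between SC and CME or between CP and CM. From SC to CME 24 tiles were higher and 10 lower. From CME to CP 25 were higher and 2878 lower (3.38%). From CP to CM 26 were higher and 19 lower. The first and last steps thus held 0.0400% and 0.0529% of tiles. Over the whole course, WT CM had 107 tiles higher and 2393 lower than WT SC. Of the 2393, 1909 (79.8%) were also lower in WT CP than in WT CME, a pair that shares no library with the first, where independent lists would share 80.9. Both pairs set a library without the suffix against one with it, so a set effect would raise this overlap too, and stage and set are not separated in either. At 40 points it held 886 lower tiles, and WT CM minus WT SC held 909.

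The largest losses over the course were at 97583001 on chromosome 7, from 93.0% of 114 reads in WT SC to 2.12% of 189 reads in WT CM, and at 11227001 on chromosome 16, from 91.0% to 1.81%. Tiles at 80899001 on chromosome 10 (88.6% to 1.004%), 18517001 on chromosome 1 (94.5% to 8.23%), 28907001 on chromosome 2 (90.7% to 4.59%) and 46831001 on chromosome 21 (89.9% to 4.57%) followed. In WT CP these 6 tiles already stood at 11.6%, 4.19%, 5.47%, 10.8%, 2.06% and 4.14%. In TKO CP they stood at 94.5%, 89.7%, 93.2%, 74.1%, 91.2% and 92.9%. Gains were led by 995001 on chromosome 19 (13.8% to 93.6%), 28725001 on chromosome 6 (22.6% to 84.7%) and 4763001 on chromosome 17 (17.4% to 78.0%). Then came 31138001 on chromosome 6 (5.82% to 57.3%), 38297001 on chromosome 8 (11.7% to 61.7%) and 87141001 on chromosome 2 (45.0% to 92.3%). As a mean over CpGs, WT CM exceeded WT SC by 16.8 points at 995001 on chromosome 19 and by 16.7 points at 87141001 on chromosome 2, so neither passed 25 points by that measure. By the same measure 67 of the 107 gains were called, and 2034 of the 2393 losses. The gains made up 0.126% of tiles.

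Tiles lower in WT CM than in WT SC had high median levels in all 3 TKO libraries. At the 2393 tiles lower in WT CM than in WT SC, the median level was 81.5% in WT SC, 79.5% in WT CME, 38.6% in WT CP and 38.8% in WT CM. In TKO it was 85.2% at SC, 85.2% at CME and 89.3% at CP. TKO CP was 25 points or more below TKO SC in 8 of these tiles (0.334%) and as far above in 3, with a median change of 3.56 points (interquartile range 0.3001 to 6.46). Of the 2393 tiles, 2126 (88.8%) were higher in TKO CP than in WT CP, and their median difference over all 2393 was 47.2 points. Independent lists would share 287, a low bar, since WT CP stood near WT CM at these tiles. The TKO and WT CP libraries had no part in choosing these tiles, but the choice itself rests on a pair that differs in the suffix.

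**Figure D3:**
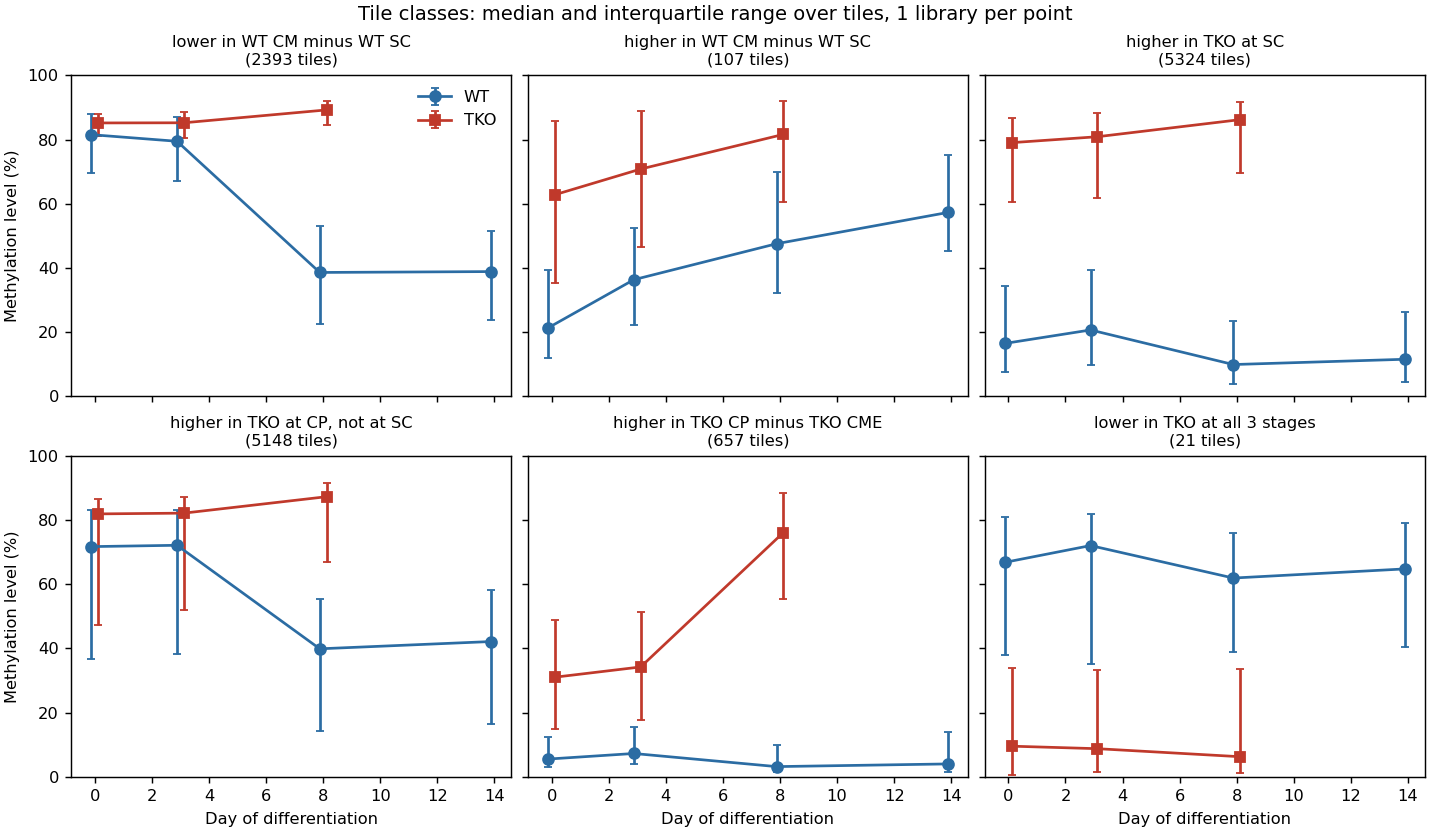
Methylation level (%) against day for 6 classes of tiles, as the median (points) and interquartile range (bars) over tiles, with 1 library per point, WT as circles and TKO as squares. In the 2393 tiles lower in WT CM than in WT SC, the WT median was 79.5% at CME and 38.6% at CP while the TKO median was 85.2% and 89.3%.

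Among the TKO libraries, most tiles that differed were higher in CP than in CME, with 1 library at each stage. From TKO SC to TKO CME 19 tiles were higher and 16 lower, 0.0411% of tiles. From TKO CME to TKO CP 657 were higher and 51 lower. The 657 tiles had medians of 31.1% in TKO SC, 34.2% in TKO CME and 76.2% in TKO CP, and of 5.51%, 7.25%, 3.16% and 3.99% in WT SC, CME, CP and CM. Thus 553 of them were under 20% in WT SC. The median tile also moved by 1.497 points between these libraries. At 40 points 186 tiles were higher and 4 lower.

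The tiles higher in TKO at SC formed 4221 regions, of which 3373 were a single tile, and the tiles lost in WT formed 2267 regions, 2157 of them a single tile. Of the single tiles, 1780 of the 3373 and 1378 of the 2157 had no measured tile directly beside them, so the extent of those changes is unknown. The region higher in TKO at SC with the most called tiles, singled out after its values were seen, spanned chromosome 22 from 19746001 to 19755000. Its 8 called tiles, with 266 CpGs, stood at 5.24%, 7.33%, 3.57% and 4.30% in WT SC, CME, CP and CM and at 76.3%, 78.4% and 82.7% in TKO SC, CME and CP. Between them, 73 CpGs from 19748247 to 19748969 remained at 1.13%, 2.26% and 2.72% in TKO SC, CME and CP. A region on chromosome 1 from 2983001 to 2991000 (7 tiles) stood at 5.59% in WT SC and 91.1% in TKO SC over those tiles. At CP the most called tiles were on chromosome 15 from 53075001 to 53084000 (9 tiles), at 2.24% in WT CP and 14.9%, 19.3% and 48.5% in TKO SC, CME and CP. The region lost in WT with the most called tiles, on chromosome 11 from 1986001 to 1992000, stood over its 5 called tiles at 67.8% in WT SC, 70.3% in WT CME, 27.1% in WT CP and 24.5% in WT CM, and at 81.1%, 82.1% and 82.8% in TKO. Its other 9 CpGs, from 1987275 to 1987961, stayed at 96.5%, 90.9%, 95.7% and 93.4% in WT, and the whole span stood at 70.2% in WT SC and 33.1% in WT CM.

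**Figure D4:**
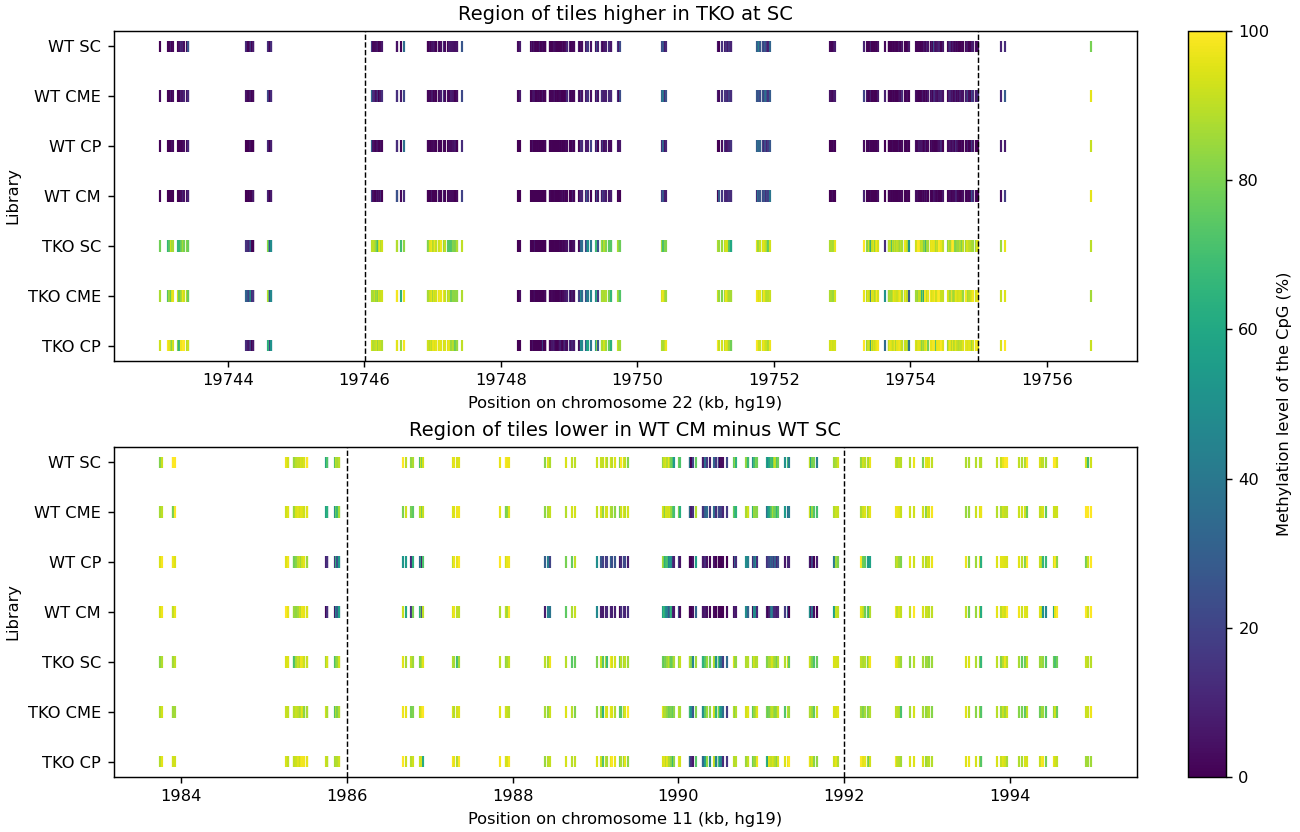
Methylation level (colour, %) of each CpG with 10 or more reads in all 7 libraries, by position (kb, hg19) and library. Dashed lines mark the regions on chromosome 22 (19746001 to 19755000, 5.24% in WT SC and 76.3% in TKO SC over its called tiles) and chromosome 11 (1986001 to 1992000, 70.3% in WT CME and 27.1% in WT CP over its called tiles).

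How often tiles changed varied with their CpG number. Counting CpGs seen in any library, WT loss took 4.15% of tiles with 5 to 9 CpGs, 3.56% of those with 10 to 19, 1.38% of those with 20 to 39 and 0.111% of those with 40 or more. Gain in TKO SC took 3.99%, 6.59%, 10.03% and 6.18% of the same classes, and gain in TKO CP 10.8%, 13.3%, 14.97% and 8.56%. Starting level differs between these classes. Among tiles under 20% in WT SC, gain in TKO CP took 25.5%, 19.1%, 14.5% and 6.87%, and among tiles over 80%, WT loss took 3.06%, 3.11%, 1.84% and 0.409%, so both were rarest in the tiles with the most CpGs. Over CpGs under 20% in both WT SC and WT CME, TKO CP exceeded WT CP by a mean of 17.0 points within 500 bp of the nearest measured CpG over 80% and by 6.26 points at 2000 bp or more. In tiles of 40 or more CpGs the means were 18.99 and 4.14 points, and in tiles of under 20 CpGs they were 8.69 and 13.8, in the opposite order.

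**Figure D5:**
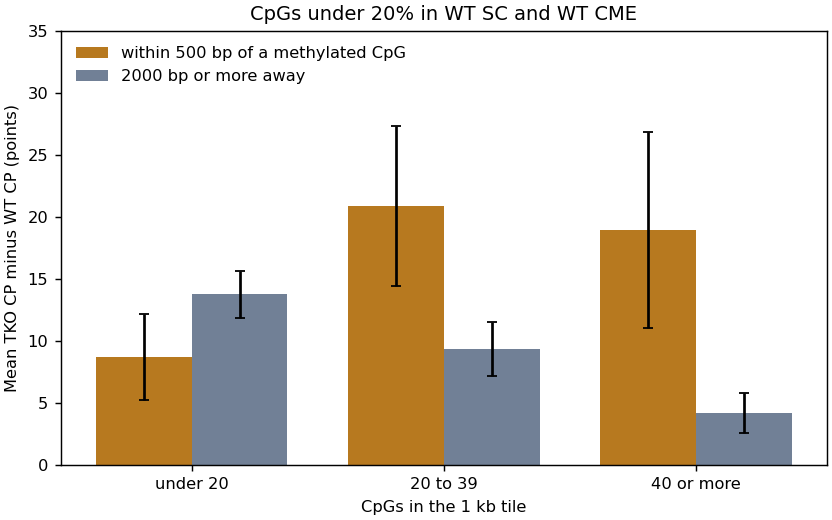
Mean TKO CP minus WT CP level (points) of CpGs under 20% in WT SC and WT CME, by number of CpGs in the 1 kb tile, for CpGs within 500 bp of a CpG over 80% in WT SC and for those 2000 bp or more away. Error bars are the SD of the means of 22 autosomes; the means were 18.99 and 4.14 points in tiles of 40 or more CpGs.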

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

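The tests of library set and of conversion in this part were chosen after the results were seen, and the tests of depth and of a shift of the whole library were written before.

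The TKO minus WT difference changed with stage, which marks these tile counts for a closer look. It was larger at CP than at SC in 4827 tiles and smaller in 92, larger at CP than at CME in 4821 and smaller in 50, and larger at CME than at SC in 22 and smaller in 40. The change to CP is confounded with a possible library set, since WT SC and WT CME carry the suffix in their descriptions and WT CP does not. A second group of values comes from data outside the comparisons. The share of C reads at 38 mitochondrial CpGs lay above the limit that a count of 0 allows in each library, at 1.504% in WT SC (95% Wilson interval 1.47 to 1.54) and 1.46% in WT CME, against 0.219% in WT CP, 0.216% in WT CM, 0.142% in TKO SC, 0.397% in TKO CME and 0.139% in TKO CP. The 2 libraries with the higher share are those whose descriptions carry the suffix.

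WT CP was lower than WT CME at 2878 tiles, the same step at which the suffix is lost. Had the set without the suffix lowered values by as much as each tile's loss, no TKO library of that set could exceed 100% minus the loss, whatever the genotype. In 92.3% of the tiles (2657) both TKO CME and TKO CP did, with medians of 85.5% and 89.4%. Unconverted cytosine differed by 1.29 points between WT SC and WT CP, far less than the 25 points a call needs. These values argue against a lowering by the same number of points in WT and TKO, and against conversion, as the whole cause. The bound does not cover a set effect that shrinks towards the ends of the scale, which was not tested. For values raised in WT SC and WT CME the number of TKO libraries with the suffix, 0 of 3, leaves no test, so this and the loss with stage cannot be told apart, nor was a difference between the WT cultures tested.

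TKO exceeded WT at SC and CME, where the WT libraries carry the suffix and the TKO libraries do not. Had the set without the suffix raised values by as much as the difference at CME, WT CP would lie at or above that difference. In 88.6% of the 5121 tiles (4538) it lay below, with a median of 9.04%. Unconverted cytosine would raise the level, yet its share in TKO SC minus WT SC was -1.36 points. These values argue against a rise by the same number of points in WT and TKO at CME, and against conversion, as the whole cause. A set effect that shrinks towards the ends of the scale was not tested here either. Had the values instead been lowered in WT SC and WT CME, WT CP and WT CM would stand near TKO. Both lay 25 points or more below TKO SC in 94.6% of the 5324 tiles higher there, and below TKO CME in 96.8% of the 5121, which argues against that as the whole cause. Lowered values together with a fall in WT by CP were not tested. TKO CP and WT CP, taken as 1 set, differed in 95.1% of the tiles higher at SC, and clonal differences between 1 WT and 1 TKO culture were not tested.

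TKO CP exceeded TKO CME at 657 tiles, with both libraries taken as 1 set. After subtracting the median difference of all tiles, 89.0% of them (585) were still called, and after thinning both libraries to the same reads per CpG 90.1% (592) were. The median difference was 1.497 points, far less than the 25 points a call needs, so its subtraction could remove few calls. That size argues against a uniform shift as the whole cause, and the count kept adds nothing to it. At full depth no tile differing by 25 points or more failed the adjusted p. Thinning could thus remove few calls too, so it does not decide whether depth had a part. A gain with stage in TKO cells may remain as a hypothesis, alongside a difference between the TKO cultures, which was not tested.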

How the results depend on the processing

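Of the alternatives used here, correction for the mitochondrial share of C, weighting the overall level by reads, thinning of the comparison between CP and SC and the fit with stage as block were chosen after seeing the data. The level of each library moved under each alternative by more than 0.00928 points, the widest counting interval of the read-weighted levels. That interval belongs to another measure and is so narrow that almost any change of CpGs exceeds it, so the sizes below say more. No interval was computed for the mean over CpGs. In the order WT SC, CME, CP and CM and TKO SC, CME and CP it was 45.4%, 46.5%, 40.6%, 40.6%, 48.7%, 48.2% and 48.03% over all CpGs of a library. It was 37.9%, 38.5%, 35.4%, 35.8%, 40.7%, 41.1% and 43.1% at a minimum of 20 reads, and 41.9%, 42.6%, 39.4%, 39.8%, 44.5%, 44.9% and 46.96% on the autosomes. After correction for the mitochondrial share it was 41.4%, 42.04%, 39.2%, 39.7%, 44.3%, 44.6% and 46.8%, and weighted by reads 33.9%, 33.8%, 28.02%, 28.7%, 36.7%, 33.3% and 37.3%. TKO lay above WT at each stage in all of these except at CME when weighted by reads. The course within TKO depended on the alternative. Over all CpGs of a library TKO did not rise to CP, and weighted by reads it fell from SC to CME before rising to CP. The cause of these shifts was not tested.

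Higher calls outnumbered lower calls in the 3 genotype comparisons, and lower calls outnumbered higher ones in WT CP minus CME and WT CM minus SC, under each alternative, all of which keep a minimum difference. By adjusted p alone the direction turned for TKO minus WT at SC (14578 higher, 20114 lower) and CME (14060 and 23587), and not at CP (33428 and 3058). Counts by adjusted p alone were not recomputed after correction for the mitochondrial share of C, so its part in those counts was not tested. In tiles over 80% in WT CP the median difference was -3.10 points at SC and -3.55 at CME. These falls exceed the shares of 1.504% in WT SC and 1.46% in WT CME, which argues against conversion as the whole cause in those tiles. At a difference of 40 points, which by construction calls fewer tiles, the higher and lower counts were 3393 and 20 for TKO minus WT at SC, 3212 and 18 at CME, 6631 and 12 at CP. For WT they were 0 and 0 for CME minus SC, 4 and 886 for CP minus CME, 0 and 1 for CM minus CP and 16 and 909 for CM minus SC, and for TKO 1 and 1 for CME minus SC and 186 and 4 for CP minus CME. Agreement of both strands could be tested in 42050 tiles, and gave 2882 and 25 for TKO minus WT at SC, 2824 and 20 at CME and 4543 and 16 at CP. For WT it gave 8 and 0 for CME minus SC, 3 and 560 for CP minus CME, 1 and 2 for CM minus CP and 21 and 483 for CM minus SC, and for TKO 1 and 1 for CME minus SC and 370 and 15 for CP minus CME. Of the main calls in those tiles, both strands passed in 87.2% of the TKO CP gains, 66.3% of the WT losses from CME to CP and 71.1% of those from SC to CM.

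At a minimum of 20 reads (66765 tiles), WT CME minus SC had 6 lower tiles, WT CP minus CME 12 higher, WT CM minus CP 10 higher and 11 lower, and TKO CME minus SC 10 higher, against 13 lower. Over the CpGs of the 2 libraries compared, TKO CME minus WT CME had 118 lower tiles, WT CME minus SC 17 lower, and TKO CME minus SC 35 higher and 37 lower. WT CP minus CME had 9 higher tiles as a mean over CpGs and 14 after thinning, and WT CME minus SC had 39 higher in 500 bp tiles. The cause of these shifts was not tested. Choosing the WT losses at 40 points left 909 tiles. The genotype difference at a minimum of 20 reads was larger at CME than at SC in 9 tiles and smaller in 25, smaller at CP than at CME in 30, and smaller at CP than at SC in 48, or in 33 after thinning. All other counts stayed within 1.5 times the main count, among them the tiles higher in TKO CP (8279 to 12035) and those lost from WT CME to CP (2068 to 3365) apart from the strand and 40 point settings. With stage as block, 5298 tiles were higher and 29 lower in TKO, against 4645 and 21 called at all 3 stages. Within a stage there are no replicate pairs. Leaving out a library would remove the comparisons it enters. The alternatives planned for promoters and gene lists were not run. Depth limits the small tiles, where the intervals of the tiles named reached ± 10.1 points.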

Other observations

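In this part, the test in tiles of under 20 CpGs and the test of gains shared by WT and TKO were chosen after the results were seen.

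Tiles at intermediate levels shifted upwards in TKO cells. Of 416 tiles between 40 and 60% in all 4 WT libraries, 117 were over 80% in all 3 TKO libraries, 66 stayed within the range in all 3 and 0 of 416 were under 20% in all 3. Their median was 68.7% in TKO SC and 75.1% in TKO CP. At SC, 160 of them were called higher and 6 lower.

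The share of tiles that changed varied between chromosomes, which was not tested and not adjusted for CpG number or starting level. TKO CP was higher than WT CP in 7.68% of tiles on chromosome 13 and in 14.2% on chromosome 15, the extremes among the 23 chromosomes compared. WT loss from SC to CM ran from 1.18% on X to 3.99% on chromosome 16.

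A hypothesis was tested that methylation in TKO cells enters unmethylated stretches from their methylated flanks. Over all CpGs under 20% in WT SC and WT CME, those within 500 bp of a methylated CpG gained more than those 2000 bp or more away in 22 of 22 autosomes. Lower CpG density per tile beside the flank would predict little difference among dense tiles, yet in tiles of 40 or more CpGs the near CpGs gained 14.8 points more (SD over autosomes 7.60). That class counts CpGs over the whole tile and has no upper limit. Density right beside the flank was thus not held fixed, so this does not set density aside. In tiles of under 20 CpGs the order was the other way, and near CpGs gained more in 2 of 22 autosomes, so the hypothesis fails there. CpGs closest to the flank, within 200 bp, exceeded WT CP by 8.39 points, less than the 19.8 points at 200 to 500 bp. The gain also varied with the width between the flanking methylated CpGs. Its mean was 9.84 points under 1000 bp, 17.2 points at 1000 to 2000 bp and 6.36 points at 10000 bp or more. CpGs far from a flank lie only in wide stretches, so distance and width were not separated. Spread from the flank may apply to dense stretches, as a hypothesis, and distance is known only to the nearest CpG that was measured.

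The 107 tiles gained in WT cells from SC to CM were already high in TKO stem cells in many cases, with 69 (64.5%) at 50% or more in TKO SC. If the gain needs no TET enzyme, the other 38 would rise in TKO cells too. Of these, 18 (47.4%) were 25 points or more higher in TKO CP than in TKO SC, against 2.44% of the 28723 tiles under 50% in TKO SC. This lies between the bounds set for the test, so it leaves the question open, and TKO cells had no CM stage to compare. The tile at 31138001 on chromosome 6 stood at 1.82%, 11.5% and 39.5% in TKO SC, CME and CP and at 5.82%, 10.3% and 39.6% in WT. That at 28725001 on chromosome 6 stood at 14.5%, 40.4% and 25.7% in TKO and at 22.6%, 33.8% and 81.9% in WT.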
